A study of Caenorhabditis elegans with 6 samples.

How the data were processed

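The measurement was the number of RNA-seq reads per gene in whole Caenorhabditis elegans. The series compared nmr-2(ok3324), a deletion allele of a subunit gene of the NMDA-type glutamate receptor, with the wild-type strain N2 (WT). Each genotype had 3 libraries, all labelled L4, the last larval stage. Per the labels' protocols, animals were synchronised by letting about 40 gravid adults lay eggs for 3 h on 10 cm plates seeded with the OP50 strain of Escherichia coli at 20 °C, washed in M9 buffer and frozen in QIAzol, and RNA was taken with an RNeasy Plus Universal kit and treated with TURBO DNase before Illumina sequencing.

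Each library came as a table of whole-number counts per gene, deposited by the authors without normalization. HTSeq and DESeq2 are named, per the submitters' processing notes, with no version. The aligner, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. Genes that overlap on opposite strands therefore cannot be told apart, and members of families with near-identical copies (collagens, abu, idpc and pqn genes, histones, major sperm protein genes) can share or lose reads. The tables hold 46911 gene identifiers, of which 27448 had no count in any library. Names came from a table that paired 44059 of them with a symbol, and coordinates from the WBcel235 annotation of Ensembl release 115, which holds 46863. Totals ran from 21234748 to 27893186 counts per library, and ribosomal RNA genes took 5.58% to 10.2% of them. At these depths 3 counts correspond to 0.108 to 0.141 CPM (counts scaled to 1e+06 per library). Intervals given for counts cover counting error only.

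Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the genotype as group, with nmr-2 kept in any case, which left 13138. Libraries were scaled by TMM factors, and the quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest) was applied with Benjamini-Hochberg adjustment at 0.05. The words rose and fell are used for genes past this threshold, or, where said, past 0.05 with the adjustment made over 1 list alone. The standard error (SE) of a log2 fold change was taken as its absolute value divided by the square root of F. CPM values use the TMM factors, and log2 CPM a prior count of 2. Nothing in the labels says that the 3 libraries of a genotype came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Pairs of libraries of 1 genotype differed beyond sampling noise, with a chi-square per degree of freedom of 10.2 to 45.9, so each library was counted as 1 replicate.

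Before the data were examined, 46 gene lists, the tests and the rule for named genes were fixed. The rule takes nmr-2, the 12 genes with the greatest absolute log2 fold change in each direction among those past the threshold with a mean of at least 1 CPM and non-overlapping groups, and up to 4 members with the smallest p of each list past its own threshold and of the glutamate receptors and transporters. Genes named outside that rule are said to be so. Lists with 3 or more tested members (45 of the 46) were tested with camera from limma 3.58.1 on the edgeR object with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which tests whether the genes of a list move on balance 1 way (directional) or change in either direction (mixed), without comparing them with other genes. The mitochondrial genome list was taken by chromosome. The medians of the 13 lists that passed and of the glutamate list were followed through the alternatives one by one. Those of the other 31 tested lists were computed too, and the choice to give them only as a count was made after they were seen: 21 of these lists had a median that changed sign under at least 1 of 13 alternatives. Positions were compared with 2-sided Fisher exact tests.

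On simulated counts with the means, dispersions and library sizes of these 6 libraries and 200 genes changed, the edgeR step, run on 12896 genes, recovered 37.3% of the genes changed 1.5-fold, 67.2% of those changed 2-fold and 93.9% of those changed 4-fold. It made 7 false calls among 139. The camera step called 0 lists there, where genes varied independently.

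The alternatives were DESeq2 1.42.0, limma-voom, size factors of the DESeq2 kind (RLE), library totals without a scaling factor, no low-count filter, a filter of 1 CPM in 3 libraries, glmTreat against a fold of 1.5, the replicate number as a block, leaving out each library, and windows of 1 and 4 Mb around nmr-2 in place of 2 Mb. Added after the data were examined were the fit without both libraries numbered 2, the fit without the cuticle lists and families, gene families by name with 5 or more tested members (335 families, 1-sided Fisher exact tests), and windows of 50 kb along the chromosomes. Figures were drawn with matplotlib 3.10.9.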

Results

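RNA was sequenced from whole animals of the C. elegans strain nmr-2(ok3324), which carries a deletion in a gene for an NMDA-type glutamate receptor subunit, and from wild-type N2 animals (WT). Both were labelled L4, and each genotype had 3 libraries. Totals were 27893186, 22407837 and 21234748 counts in nmr-2(ok3324) replicates 1, 2 and 3, and 23070856, 24609118 and 25202816 in WT replicates 1, 2 and 3. The single comparison asked how loss of this receptor subunit alters transcript levels in animals labelled L4. Log2 CPM values correlated across genes at 0.983 to 0.987 on average with libraries of the same genotype and at 0.975 to 0.982 with those of the other. Scaling factors lay between 0.987 and 1.01 in 4 libraries, and stood apart at 1.20 in nmr-2(ok3324) replicate 2 and 0.838 in WT replicate 2.

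The deleted gene itself was near the limit of detection. nmr-2 (WBGene00003775, chromosome V, 15006341 to 15011660 in WBcel235, minus strand) had 3, 5 and 5 counts in the mutant libraries and 7, 2 and 10 in the WT libraries. The 13 against 19 counts give a ratio of 0.618 with a 95% exact interval of 0.281 to 1.32. The fitted log2 fold change was -0.64 (SE 0.74, edgeR adjusted p = 0.66). A difference in nmr-2 was not detectable at this depth, and these counts do not check the genotype labels.

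In nmr-2(ok3324) animals 235 genes rose and 49 fell, among 13138 tested with edgeR. Of these, 182 rose and 20 fell by 2-fold or more. The groups did not overlap for any of the 284, as held for 24.4% of all tested genes, where chance gives 10%. At an unadjusted p under 0.05 there were 2257 genes. Tested against a fold of 1.5, 131 genes changed. Without the low-count filter 596 did, in a fit whose prior degrees of freedom were infinite for 17093 of 19463 genes, against a median of 11.2 with the filter, so that its p-values leave out most of the spread of single genes. Without both libraries numbered 2, an alternative added after the data were examined, 530 genes changed, 345 up and 185 down, with 2 residual and a median of 35.2 prior degrees of freedom. The 235 became 154 without nmr-2(ok3324) replicate 1 and 151 without WT replicate 3, and the 49 became 30 without WT replicate 1, 105 with DESeq2 and 16 with library totals alone.

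**Figure D1:**
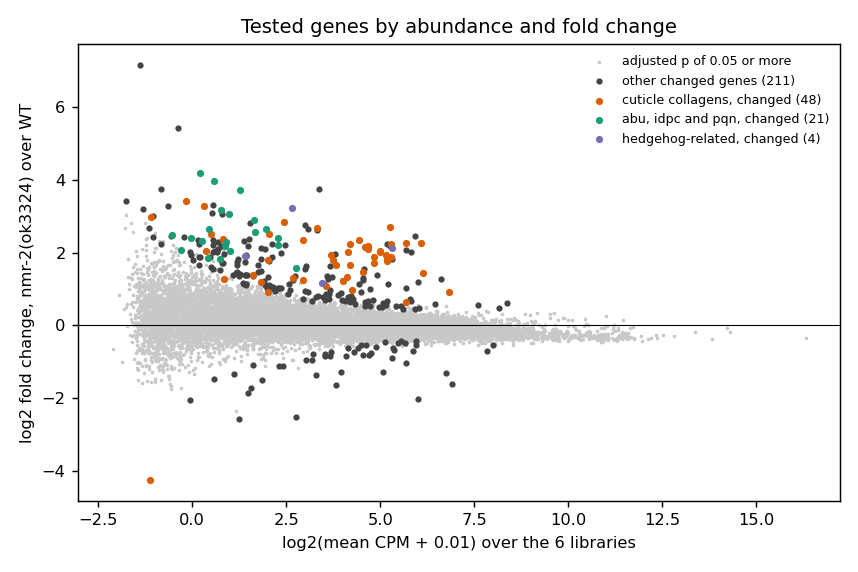
Log2 fold change of nmr-2(ok3324) over WT (vertical) against log2 of the mean CPM plus 0.01 over the 6 libraries (horizontal), 1 point per tested gene, with the 284 changed genes coloured by group. Changed collagens lie above 0 except for 1, and the grey cloud slopes from a median of 0.30 in the 10% of genes with the lowest levels to -0.19 in the 10% with the highest.

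Cuticle collagen genes made up the main group that rose. Of 118 tested members of this list, which encode the structural proteins of the worm's exoskeleton, 47 rose, 1 fell and 70 did not pass. Adjusted over the list alone, 56 rose and 2 fell. The smallest p-values belonged to col-138, at 85.3 ± 13.9 CPM in the mutant and 17.9 ± 2.02 in WT (SD, n = 3; log2 fold change 2.26, SE 0.14, edgeR adjusted p = 2.6e-07), and to col-77, at 113 ± 14.9 and 23.5 ± 4.87 CPM (2.27, SE 0.15). They were followed by col-14 (2.05, SE 0.15) and col-65 (2.69, SE 0.21). The 47 risen collagens together went from 491 ± 92.5 CPM in WT to 1597 ± 241 CPM in the mutant, a 3.25-fold difference. The other 71 collagens held most of the collagen RNA, 41341 ± 6724 CPM in WT and 40263 ± 6657 CPM in the mutant. The 1 collagen that fell, dpy-14, was named after its values were seen: it had 3 counts over the mutant libraries and 58 over the WT libraries, a ratio of 0.0468 (95% exact interval 0.00937 to 0.144). By camera the list's median log2 fold change of 0.52 stood above that of other genes (adjusted p = 3.1e-48), and adjusted p = 0.64 with an estimated correlation. Between 36 and 57 collagens rose under each alternative that kept them in the fit.

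Hedgehog-related genes, many of which encode secreted proteins of epithelia, moved the same way in part. Of 28 tested, 4 rose and 0 fell, and 24 did not pass; adjusted over the list alone, 8 rose and 1 fell. grl-16 rose from 14.8 ± 1.99 to 64.6 ± 9.59 CPM (log2 fold change 2.12, SE 0.14), and the others were grd-6 (3.22, SE 0.35), grd-14 (1.16, SE 0.18) and wrt-4 (1.92, SE 0.30). Camera placed the list above other genes (median 0.40, adjusted p = 1.4e-05), with adjusted p = 0.66 with an estimated correlation. In the list of molting cycle genes, mlt-8 (1.25, SE 0.24; named after its values were seen) rose and 17 did not pass; adjusted over the list alone, 2 rose and 1 fell.

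Gene families formed by name, tested after the data were examined, added groups outside the fixed lists. All 10 tested abu genes, named for activation when the unfolded protein response is blocked, rose, with log2 fold changes of 1.84 to 3.18 (1-sided Fisher exact test, adjusted p = 4.6e-16 over 335 families). All 7 idpc genes rose as well, by 2.17 to 3.97 (adjusted p = 6.0e-11), and 42 of 103 col genes (adjusted p = 1.7e-44). No other family passed among risen genes, and none among fallen genes. Members of abu, pqn and idpc supplied 6 of the 12 greatest rises among genes with a mean of at least 1 CPM: pqn-2 (log2 fold change 4.18, SE 0.55), idpc-5 (3.97), idpc-3 (3.72), abu-7 (3.18), idpc-6 (3.07) and abu-11 (2.89). All were rare transcripts, with a mean of 1.14 to 3.08 CPM, and reads can be shared within each family. The other 6 were H10E21.4 (3.76, SE 0.28), Y43F8B.3 (3.31), col-174 (3.30), grd-6, D2096.6 (3.09) and T19A5.3 (3.06). The call of abu-7 was lost with DESeq2. The log2 fold change of abu-7, whose WT counts were 21, 0 and 2, was 5.97 without WT replicate 1.

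**Figure D2:**
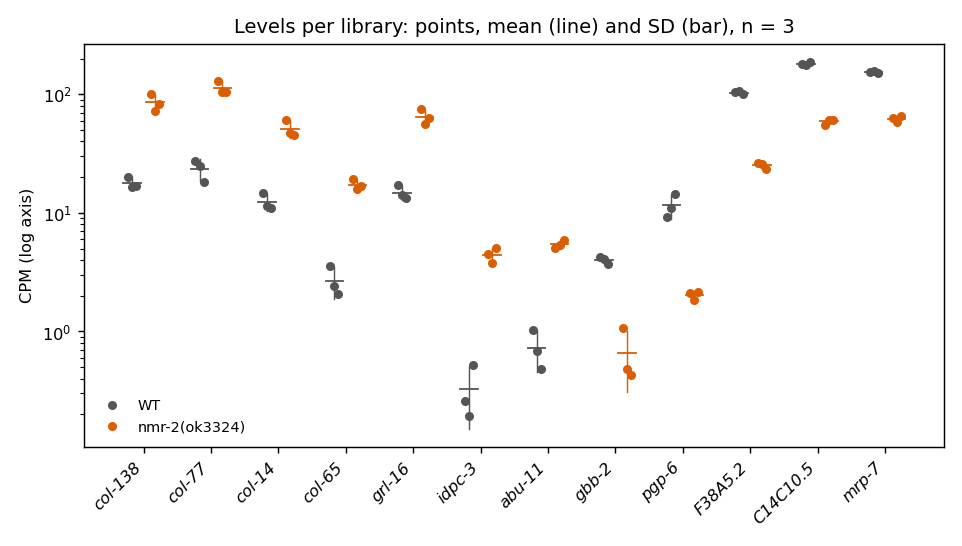
CPM per library on a log axis for 12 of the named genes, with WT in grey and nmr-2(ok3324) in orange; points are libraries, horizontal lines means and vertical bars the SD (n = 3). For each gene shown, the 3 libraries of one genotype lie apart from the 3 of the other, higher in the mutant for the 7 genes on the left and lower for the 5 on the right.

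Among the 49 genes that fell, the greatest decrease with at least 1 CPM was in gbb-2, which encodes a GABA-B receptor subunit. It went from 4.03 ± 0.29 CPM in WT to 0.659 ± 0.352 CPM in the mutant (log2 fold change -2.57, SE 0.34, edgeR adjusted p = 0.00029), a 5.95-fold difference. The ABC transporter gene pgp-6 was next (-2.51, SE 0.22). Another, mrp-7, was the last of the 12 named decreases, at 154 ± 4.05 CPM in WT and 61.9 ± 3.84 CPM in the mutant (-1.32, SE 0.10). F38A5.2 had the smallest p of all tested genes, at 103 ± 3.17 CPM in WT and 25.3 ± 1.72 CPM in the mutant (-2.03, SE 0.11, adjusted p = 6.3e-08), and C14C10.5 went from 181 ± 4.68 to 59.2 ± 3.23 CPM (-1.62, SE 0.10). The fatty acid desaturase gene fat-5 (-1.36, SE 0.17) and the lipid-binding protein gene lbp-3 (-1.64, SE 0.17) fell too. The rest of the 12 were the ciliary gene dyf-3 (-1.87), C18D4.6 (-1.72), a pseudogene without symbol, WBGene00021055 (-1.51), F31E9.6 (-1.49) and nspe-1 (-1.33). The call of F31E9.6 was lost without any 1 library other than WT replicate 2, that of nspe-1 without replicate 2 or 3 of either genotype, both with limma-voom, and those of WBGene00021055, F31E9.6 and nspe-1 with library totals alone.

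No gene of glutamate signalling passed by itself. Of 16 tested glutamate receptor and transporter genes none was called by edgeR, DESeq2 or limma-voom, and 3 had an unadjusted p under 0.05. The smallest p-values were those of glt-6, a glutamate transporter gene (0.89, SE 0.34, edgeR adjusted p = 0.21), mgl-2, a metabotropic receptor gene (0.73, SE 0.30, adjusted p = 0.25), glc-4 (0.80, SE 0.36) and glt-7 (0.84, SE 0.48). The list's median was 0.40, with a camera adjusted p of 0.15; by fry the adjusted p was 0.12 for a shared direction and 0.045 for change in either direction. The low-count filter left 16 of 29 genes of this list to be tested. It left 16 of 1294 chemoreceptor genes, 9 of 32 cilium markers, 21 of 37 acetylcholine and GABA receptor genes and 45 of 71 neuropeptide-like protein genes. Nothing is known here of the rest. In the other neuronal lists, named members were singled out after their values were seen. 1 of 21 acetylcholine and GABA receptor genes fell (gbb-2), 2 of 45 neuropeptide-like protein genes rose (nlp-67, log2 fold change 2.02, and nlp-29, 1.33, an epidermal antimicrobial peptide gene), 1 of 16 chemoreceptor genes fell (sri-40, -0.61), and 1 of 9 cilium markers of sensory neurons fell (dyf-3). With library totals alone 1 neuropeptide-like protein gene and 0 chemoreceptor genes were called. Calls in the lists for postsynaptic and calcium signalling (21 tested), synaptic vesicle release (23), neurotransmitter synthesis and transport (14), FMRFamide-like neuropeptides (30), insulin-like peptides (13) and pan-neuronal markers (9) numbered 0 with edgeR, and 1 with DESeq2, in postsynaptic signalling. At an unadjusted p under 0.05 these 6 lists held 6, 4, 1, 1, 0 and 2 genes. Adjusted over the list alone, 1 postsynaptic gene and 3 neuropeptide-like protein genes rose, and 0 glutamate genes.

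Ribosomal, proteasome, oxidative phosphorylation, oogenesis, germline proliferation and yolk protein lists had medians below 0. By camera, 13 of 45 lists passed, 4 higher and 9 lower, and 0 with an estimated correlation or with fry's directional test. Fry's mixed test, which asks for change in either direction, passed 15 lists, of which 5 had passed camera and 10 had not. Among the 5 were hedgehog-related genes (fry mixed adjusted p = 0.0025), collagens (0.0029) and C-type lectins (0.020). Among the 10 were cilium markers of sensory neurons, DAF-16 targets and glutathione metabolism (0.0011 each), fatty acid synthesis (0.0044) and acetylcholine and GABA receptors (0.0059). By edgeR 1 of 9, 2 of 12, 4 of 41, 1 of 21 and 1 of 21 of their genes were called, with fat-5 in both the DAF-16 and the fatty acid list. Whether these single genes carry the mixed results was not tested. The camera adjusted p of the 32 lists that did not pass camera lay between 0.052 and 0.998. Ribosomal protein genes had a median log2 fold change of -0.31 and were negative in 76 of 80 (camera adjusted p = 3.7e-11, adjusted p = 0.69 with an estimated correlation), yet 0 of them fell by themselves, 4 having an unadjusted p under 0.05 and 0 being called by DESeq2 or limma-voom. The members with the smallest p were rpl-41.1 (-0.45, SE 0.17), rps-28 (-0.34, SE 0.15), rpl-25.2 (-0.42, SE 0.18) and rps-29 (-0.36, SE 0.16). The medians were -0.26 for the proteasome (33 genes, camera adjusted p = 2.7e-08, led by pbs-4, -0.31, SE 0.10, and rpt-5, -0.39, SE 0.13; pas-2 and pas-4 at -0.35 and -0.34) and -0.25 for nuclear-encoded oxidative phosphorylation (38 genes, camera adjusted p = 1.3e-06, led by nuo-6, -0.38, SE 0.13; cox-7C, -0.43, asg-2, -0.31, and nuo-2, -0.30). Oogenesis and eggshell genes had a median of -0.29, negative in 24 of 24 (camera adjusted p = 5.2e-07; puf-11, -0.41, puf-5, -0.43, puf-7, -0.37, and egg-3, -0.27). The median was -0.17 for germline proliferation and meiosis (23 genes, camera adjusted p = 0.0077; with library totals alone 0.01, or -0.20 relative to all genes; pgl-3, -0.35, htp-1, -0.29, htp-3, -0.26, car-1, -0.43) and -0.26 for the 6 vitellogenins, the yolk protein genes (camera adjusted p = 0.019, and 0.052 without WT replicate 1; vit-4, -0.42, vit-3, -0.33, vit-1, -0.34, vit-5, -0.18). With an estimated correlation the adjusted p of these 5 lists lay between 0.66 and 0.69. No member of them passed with edgeR: at an unadjusted p under 0.05 there were 12, 7, 10, 3 and 1 genes, and DESeq2 called 3 vitellogenins. Of 10000 lists of other genes matched on abundance, a comparison chosen after the data were examined, 18.8% had a median as low as that of the germline list. The share was 18.6% for the propionate and vitamin B12 list and 0.25% for oogenesis. It was 79% for the vitellogenins, which lay above their matched genes in log2 CPM by 1.58 in the mutant and 1.60 in WT. That share therefore does not show what abundance gives at their level. Fold changes of all tested genes drifted with abundance, from a median of 0.30 in the 10% with the lowest levels to -0.19 in the 10% with the highest, and without both libraries numbered 2 from 0.17 to -0.03, where the ribosomal median was 0.03 and that of oxidative phosphorylation -0.03.

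The further lists past the camera threshold held few changed genes. Of 85 C-type lectin genes, 1 rose and 3 fell (median -0.16, camera adjusted p = 0.0041, adjusted p = 0.64 with an estimated correlation): clec-198 rose (2.43, SE 0.59), and clec-47 (-0.77, SE 0.14), clec-85 (-0.84, SE 0.18) and clec-186 (-0.46, SE 0.11) fell. Adjusted over the list alone, 3 rose and 9 fell. The calls of clec-198 and clec-186 were lost in each fit that left out 1 library, both also with limma-voom, that of clec-85 without WT replicate 1, and those of all 4 with library totals alone, where the median was 0.02, or -0.18 relative to all genes. The list's camera adjusted p was 0.082 without the low-count filter. No abundance-matched list of 10000 was as low as the C-type lectins or the histones. This matching was done only for lists that camera placed lower. For the hedgehog-related, spermatogenesis and pharyngeal lists, a rise was therefore not set apart from the upward drift of genes with low levels. Of 30 histone genes, the linker histone gene his-24 fell (-0.95, SE 0.20), a call lost with library totals alone and without nmr-2(ok3324) replicate 1 or WT replicate 1, and the others did not pass (median -0.36, and -0.02 without both libraries numbered 2; camera adjusted p = 0.00034; his-7, -1.66, his-67, -0.81, his-68, -0.46; adjusted p = 0.69 with an estimated correlation). The 11 genes of the propionate and vitamin B12 response had a median of -0.22 (hphd-1, -0.49, ech-6, -0.35, pcca-1, -0.24, alh-8, -0.39), the 38 spermatogenesis genes 0.30, and 0.15 without both libraries numbered 2 (camera adjusted p = 0.052; spe-11, 0.86, spe-49, 1.38, spe-10, 1.19, spe-42, 1.76) and the 5 pharyngeal muscle markers 0.48 (the myosin genes myo-2, 0.48, myo-1, 0.51, and myo-5, 0.71, and the troponin gene tnc-2, 0.26). Their camera adjusted p was 0.039, 0.0050 and 0.017, and their adjusted p was 0.64, 0.69 and 0.64 with an estimated correlation. No member of these 3 lists passed with edgeR; 3, 9 and 3 had an unadjusted p under 0.05, DESeq2 called 1 in each, and adjusted over the list alone 1 fell, 1 rose and 3 rose. The propionate list's camera adjusted p was 0.053 without nmr-2(ok3324) replicate 1, 0.091 without nmr-2(ok3324) replicate 3 and 0.12 without WT replicate 1, and 0.051 with a filter of 1 CPM in 3 libraries, and that of the pharyngeal list was 0.054 without nmr-2(ok3324) replicate 1.

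Of the stress, defence and metabolic lists that did not pass camera, glutathione metabolism had the most calls by edgeR. Of 41 tested genes 4 rose, all encoding glutathione S-transferases: gst-4 (1.26, SE 0.13), gst-20 (0.77), gst-24 (1.39) and gst-30 (1.81); the gst family by name did not pass (1-sided exact test, adjusted p = 0.14). These and the genes that follow were named after their values were seen. Of 58 lysozymes and antimicrobial effectors dod-24 rose (1.15) and dod-22 (-2.05) and irg-5 (-0.79) fell. Of 12 DAF-16 targets lea-1 rose (0.47) and fat-5 fell, the latter also being the 1 changed gene of 21 in fatty acid synthesis. In lists with 1 call each, fbxa-192 rose (0.79; 145 F-box and MATH domain genes), unc-89 rose (0.72; 12 body wall muscle markers), 1 of 11 genes of the mitochondrial genome rose (WBGene00010967, 0.62), ugt-62 fell (-0.48; 47 UDP-glucuronosyltransferases) and cpr-1 fell (-0.70; 10 intestine markers). With library totals alone ugt-62 and unc-89 were not called, 3 of the glutathione list and 1 of the lysozyme list were, and 5 of the 11 mitochondrial genome genes were. Adjusted over the list alone, 2 rose and 4 fell among lysozymes and among UDP-glucuronosyltransferases, 2 rose and 1 fell among DAF-16 targets, and 2 rose in each of the mitochondrial genome and body wall muscle lists. The endoplasmic reticulum (18 tested) and mitochondrial (10) unfolded protein responses, heat shock response (13), cytochrome P450s (42), intracellular pathogen response (9), fatty acid oxidation (37), hypoxia response (8), autophagy (27), major sperm proteins (43), glia markers (5) and epidermis markers (5) had 0 calls with edgeR. For 2 coelomocyte markers only values were taken, with a median of 0.57. Over the 28 lists without a call, 97 of 603 members had an unadjusted p under 0.05, DESeq2 called 8 and limma-voom 0.

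No excess of changed genes around nmr-2 was detected. Within 2 Mb of it 8 of 465 tested genes changed, 1.72% against 2.18% elsewhere (odds ratio 0.786, 2-sided Fisher exact p = 0.63), and the odds ratio was 1.39 within 4 Mb (exact p = 0.13). Of fallen genes alone 7 lay within 4 Mb, 0.753% against 0.344% elsewhere (odds ratio 2.20, exact p = 0.083, adjusted p = 0.34). On chromosome V as a whole 72 of 2399 genes changed, 3.00% against 1.97% elsewhere (odds ratio 1.54, exact test, adjusted p = 0.033 over 27 tests), and 1 of the 49 fallen genes lay on chromosome I (odds ratio 0.1, adjusted p = 0.033). The exact test counts neighbouring copies of a family as independent genes. On chromosome V, 5 changed genes lay in 1 window of 50 kb and 4 in another, windows that hold idpc and abu copies. A local run of risen genes was found at the left end of chromosome III, and its genes were named after their values were seen. Of 8 tested genes that start in the first 50 kb, 7 rose, between 3321 and 41971 bp: npr-30 (log2 fold change 1.71), nhr-80 (1.15), H10E21.1 (1.15), H10E21.4 (3.76), H10E21.5 (1.62), clp-10 and col-88 (2.69). The other, fbxa-6, had a log2 fold change of -1.39 (SE 0.60, edgeR adjusted p = 0.26). The calpain gene clp-10 had 18, 21 and 17 counts in the mutant and 0 in the WT libraries, at least 16.9-fold higher against a floor of 3 counts over the WT group, which leaves out counting error in the mutant. The 2-sided 95% exact interval of the ratio, which covers both, starts at 13.3. H10E21.1 and H10E21.4 overlap on opposite strands. Over 1971 windows of 50 kb, a test chosen after the run was seen, 1 of 10000 permutations of the calls among genes reached 7 in any window (permutation p = 2e-04, where the smallest they can give is 1e-04), and no other window held more than 5. From 5 to 7 of these genes changed under each alternative.

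**Figure D3:**
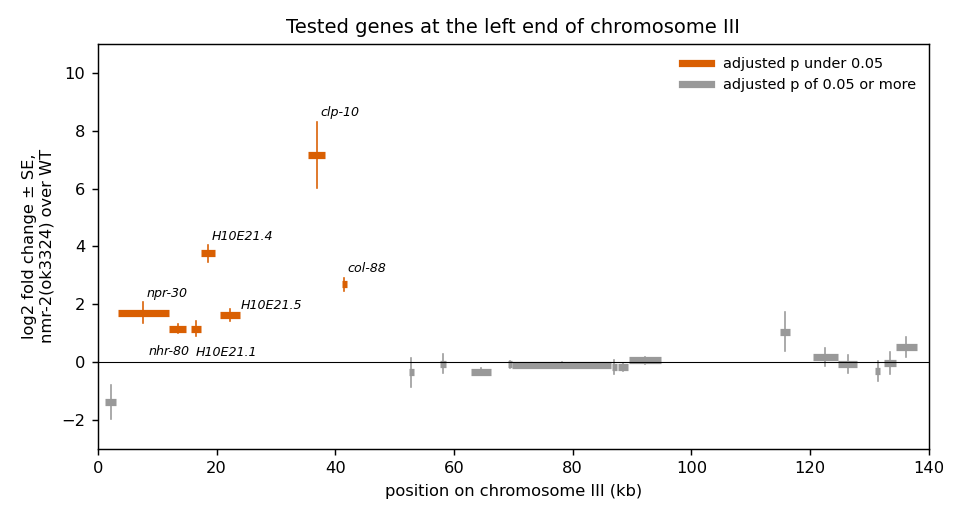
Log2 fold change of nmr-2(ok3324) over WT (vertical, bars are SE) for tested genes along the first 140 kb of chromosome III (horizontal, kb), with horizontal bars spanning each gene; orange marks the genes past the edgeR threshold. The 7 risen genes lie between 3321 and 41971 bp; the fitted value of clp-10 depends on the prior count, since its WT counts are 0.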

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

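The fit without both libraries numbered 2 and the fit without the cuticle lists and families were chosen after the data were seen. The 284 changed genes (235 up, 49 down) became 596 (441 and 155) without the low-count filter, 131 (117 and 14) with glmTreat against a 1.5-fold change, a stricter hypothesis, 530 (345 and 185) without both libraries numbered 2, and 177 (136 and 41) without the cuticle lists and families, which removes tested genes. Without the filter the prior degrees of freedom went from a median of 11.2 to infinite for 17093 of 19463 genes, and adjusted p-values of single genes fell, that for the log2 fold change of H10E21.4 from 1.1e-06 to 1.5e-63, so that count is no measure of stability. Without both libraries numbered 2 their median was 35.2. Fallen genes numbered 16 with library totals only, where the median log2 fold change of all genes moved up from 0.03 to 0.20. They numbered 105 with DESeq2, for which the cause was not tested. Leaving out 1 library gave 190 to 259 changed genes, 151 to 226 up and 30 to 52 down. DESeq2 called 282 of the 284 genes, limma-voom 249, RLE size factors 257 and library totals 188, with the same directions. Of 36 named genes past the threshold, 28 to 36 stayed past it in each setting that tested all of them, glmTreat aside, and none changed sign. nmr-2 stayed negative and short of the threshold throughout, from -1.07 to -0.23.

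Library totals moved the median of all genes from 0.03 to 0.20, and 21 lists then passed camera against 13; camera with an estimated correlation and fry's directional test each passed 0, and fry's mixed test 15. With library totals the germline proliferation and meiosis median turned to 0.0057 and that of C-type lectins to 0.018, which relative to all genes is -0.20 and -0.18. Without both libraries numbered 2 the ribosomal protein median turned to 0.033. Of 31 tested lists short of the threshold, followed here only as a count, 21 had a median that changed sign under at least 1 of 13 alternatives. The odds ratio around nmr-2 turned from 0.786 to 1.39 with 4 Mb windows (exact p = 0.13), and was 0.559 with 1 Mb; the cause was not tested. With the replicate block 142 genes changed (124 up, 18 down). The vitellogenin and propionate lists did not pass camera there (adjusted p = 0.063 and 0.083). Of the 36 named genes past the threshold, 7 lost their call with the block: col-174, F31E9.6, nspe-1, clec-85, clec-198, clec-186 and his-24. Deviations of same-numbered libraries correlated across genes at 0.0008, -0.28 and -0.10, not every library correlating best with its own number. These values give no sign that the numbers pair the libraries, but with 3 libraries per genotype they cannot exclude it. Depth limits the rare transcripts: nmr-2 had at most 10 counts in a library.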

Other observations

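Tests chosen only after the data were seen were those on the share of the fallen genes within 4 Mb of nmr-2, on abundance, on gene families by name, on windows of 50 kb and on the libraries numbered 2. The genes in the next paragraph were chosen then too. Of these tests, that of the libraries numbered 2 on the ribosomal list was set before its own value was seen. The tests of library scaling, gene length and harvest point below were not among those fixed at the start. They were set once the changed genes were known, but before their own values were seen.

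Further changed genes are given here without a test of a shared theme. Of 20 tested genes for astacin metalloproteases, some of which act in cuticle shedding, nas-27 (log2 fold change 2.42, SE 0.46), nas-30 (2.19, SE 0.34) and nas-38 (1.79, SE 0.43) rose, a family that did not pass after adjustment (1-sided exact test, adjusted p = 0.31). The peroxidase gene mlt-7 rose by 0.89 on the log2 scale (SE 0.18). On chromosome V, 5 of 12 tested genes between 9600001 and 9650000 bp rose, and 4 of 8 between 5150001 and 5200000 bp, windows that hold idpc and abu copies. R03C1.1 had 110 counts over the mutant libraries and 2 over the WT libraries, a ratio of 49.7 (95% exact interval 13.4 to 416). The yolk protein genes vit-2 and vit-6, known for expression in adult hermaphrodites, had the highest means outside ribosomal RNA, 20334 and 19231 CPM, and the oogenesis list summed to 18406 ± 2055 CPM in WT. These levels put the L4 label in doubt for both genotypes, and the harvest age was not tested.

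The 47 risen collagens were 1 pattern for which technical sources were weighed. With library totals alone their median log2 fold change was 2.08, or 1.88 above the median of all genes, against 1.93 with TMM factors. The median of all genes went from 0.03 to 0.20. A scaling factor moves all genes of a library together, so these genes, picked as risen, could hardly change their place relative to others. The values show only that the choice of factor moved medians by little beside 1.93. Gene length is argued against: 0 of 10000 lists of other genes matched on exon length and abundance reached the median of 0.52 of the 118 tested collagens, the highest being 0.03. A harvest at another point of the molting cycle cannot be told apart from a genotype effect, because each genotype has 3 libraries labelled with 1 stage: over 12916 other genes, which are not independent replicates, the slope on the collagen score within genotypes correlated with the genotype effect at -0.040, against a median of 0.0094 and a 95th percentile of 0.26 for 1000 random directions. Signs in germline and yolk lists leaned 1 way as well, but signs also went with abundance. Positive fold changes made up 67.3% of the 10% of genes with the lowest levels and 16.1% of the 10% with the highest. Of abundance-matched lists, 0.25% were as low as oogenesis and 18.8% as low as germline proliferation. The median of major sperm proteins was 0.034, near the 0.026 of all genes. Negative fold changes numbered 24 of 24 in oogenesis, 6 of 6 in vitellogenins and 19 of 23 in germline proliferation. Positive ones numbered 31 of 38 in spermatogenesis and 31 of 43 in major sperm proteins. None of these lists passed with an estimated correlation, and whether the genotypes differed in age was not tested. The hypothesis that the nmr-2 genotype itself raises cuticle genes may hold and was not tested apart from a different harvest point.

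For the 49 fallen genes, 7 lay within 4 Mb of nmr-2 (odds ratio 2.20, 2-sided exact p = 0.083), too few for linked alleles to be the source of most of them, while those 7 stay open. Their median slope on the collagen score within genotypes was 0.16, against 0.00069 for the median random direction and -0.29 for the 5th percentile, which leaves the harvest point open here too. Alleles elsewhere in the genome, as the run on chromosome III could reflect, were not tested, and neither was the genotype itself.

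The lower ribosomal protein, oxidative phosphorylation and proteasome lists may rest on the libraries numbered 2, whose scaling factors lie farthest from 1. Without both, the ribosomal median went from -0.31 to 0.033 and that of oxidative phosphorylation from -0.25 to -0.027, while the proteasome median of -0.10 leaves this open for that list. Lists of other genes matched on abundance had medians of -0.28, -0.14 and -0.17, and 0, 1 and 4 of 10000 matched lists were as low as the ribosomal, oxidative phosphorylation and proteasome lists. The matched genes were drawn outside the 13 lists past the camera threshold. The gap of each list to its matched genes differed between genotypes by -0.082, -0.13 and -0.11, against an SD within genotypes of 0.076, 0.099 and 0.044. Each gap exceeded that SD, a mark set after the data were seen. For the proteasome the 2 genotypes' libraries did not overlap in this gap, which chance alone gives in 10% of cases. They overlapped for the ribosomal and oxidative phosphorylation lists. Abundance therefore stays open for each of these lists. Ribosomal genes also lay above their matched genes in log2 CPM, by 0.15 in the mutant and 0.23 in WT. A genotype effect on these lists was not tested apart from these sources.

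The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 284 changed genes and the highest other split 0, so that 1 of the 10 reached 284. Every other split mixes the genotypes, so a genotype difference adds to the spread within its groups. The 0 is therefore no measure of what chance gives. For lists past the camera threshold, the real split gave 13 and the highest other split 17, with 5 of the 10 reaching 13.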
